A study of Arabidopsis thaliana with 8 samples.

How the data were processed

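Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was made for ENAP1 with an antibody against green fluorescent protein. The material was whole Arabidopsis thaliana seedlings of ecotype Col-0 carrying the ein3 eil1 double mutation. Per the labels, the seedlings were grown for 3 days in the dark at 24 °C and then kept for 4 h in hydrocarbon-free air or in the same air with 10 ppm ethylene. The 8 libraries formed 4 groups of 2 samples, namely air ChIP, air input, ethylene ChIP and ethylene input. The labels do not say whether samples of a group came from separate batches of seedlings.

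Per the submitters' processing notes, reads were aligned with BWA to TAIR10 and regions were called with MACS2 version 2.1.0.20150603. The labels tie 1 deposited peak list to both ChIP samples of a treatment, so each list is the authors' joint result for 2 ChIP samples, and the inputs entered as the background. The lists are named optimal by the authors, and the rule behind that choice is not given in the sources used here. Region start, region end and summit offset are positions in bp in the deposited lists, and are given here counted from 1. The deposited fold enrichment is the peak caller's ratio of ChIP pile-up to local background at the summit, with 1 added to both. It is the authors' value for each region. It was used here to describe, rank or select regions within a list and to solve the local background at each summit, and the medians of the lists are set side by side without a test. The deposited −log10 p and −log10 q values are those of the authors' peak caller against the local background. The deposited score equalled 10 times −log10 p rounded down in 100% of rows and was not used further. The numbering in the deposited region names reached 8530 in the air list and 4853 in the ethylene list, so the lists keep 53.1% and 67.9% of those numbers. Neither list holds a value per library. Total reads per library, and the pile-up and background tracks that the labels name for each treatment, were not used here.

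Every row of both lists was a distinct region on chromosomes 1 to 5, and no region was removed. Gene names, symbols and gene ends came from the RefSeq gene table of assembly TAIR10.1, without strand and without sequence. As a check that its positions fit those of the lists, summits were shifted along the chromosomes. Unshifted, 50.0% of air summits and 51.4% of ethylene summits lay up to 200 bp inside a gene end. After a shift of 200 bp in either direction the share was 18.2% to 19.6%, and after 10000 bp it was 9.90% to 10.2%. Without strand, a transcription start cannot be told from a transcription end. The tests planned around transcription starts were therefore made around both ends of a gene, and the planned classes of promoter, untranslated region, exon and intron were replaced by classes inside and outside protein-coding genes. The planned tests of motifs and of 6-mers at summits need the genome sequence and were not run.

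A gene was called bound when a summit lay from 1000 bp outside to 500 bp inside either of its ends. The 27444 nuclear protein-coding genes were the background. Regions of different lists were shared when they overlapped by at least 1 bp. Sharing was compared with 10000 random placements of the regions on their own chromosomes, and with 10000 placements at the same distance from the ends of randomly drawn genes, by a one-sided permutation p whose smallest possible value is 0.0001. Positions of summits were compared with 10000 random placements by a two-sided permutation p whose smallest possible value is 0.0002. Shares carry exact (Clopper-Pearson) 95% intervals, which cover counting error only. Before the data were examined, 17 gene lists with 275 distinct loci were fixed, and all 275 were found in the gene table. They cover ethylene signalling, ethylene biosynthesis, targets of EIN3, the ERF family, the circadian clock, jasmonate, auxin, cytokinin response, gibberellin and brassinosteroid, light signalling, photosynthesis and chlorophyll, rapid stress, histone acetylation, housekeeping, root identity, flower identity, and shoot epidermis and guard cells. The flower identity list stands for an organ absent from dark-grown seedlings. The last list also holds the shoot meristem genes STM, WUS and CLV3, and 20 loci are in more than 1 list. Each list was tested against all other genes with a two-sided Fisher exact test, separately for each peak list. Genes bound only in the air list were compared with genes bound only in the ethylene list in the same way, and Benjamini-Hochberg adjustment ran over the 17 lists, with a threshold of 0.05 on the adjusted p. Odds ratios have 0.5 added to each cell. These tests compare genes and regions of 2 lists, not replicated treatments, and neighbouring genes can share a summit.

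Genes are named by a rule fixed before the data were examined, with gene ends in place of its transcription starts, as for the tests. It takes the nearest gene of the 10 regions with the highest fold enrichment in each list and of the 8 highest air-only and ethylene-only regions, each with its summit in the window. It adds every bound member of the ethylene signalling and EIN3 target lists, up to 4 bound members with the highest fold enrichment from every other list, and the loci of ENAP1, EIN3 and EIL1.

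Because MACS2 derives both fold enrichment and p from the pile-up and the local background at a summit, these were solved for each region. In the air list all 4526 regions gave a whole-number pile-up within 0.005. In the ethylene list 72.5% of regions gave a whole-number background or the genome-wide floor within 0.005, and the median of the candidate solutions was used for the rest. Before that choice, the candidate backgrounds of a region spread by a median of 3.69% in air (95th percentile 8.12%) and 1.72% in ethylene (95th percentile 3.58%). The floor is the lowest background the caller uses over the genome and grows with the number of reads and their fragment length. It was 3.94 in the air list and 15.1 in the ethylene list. On simulated summits the solution was within 1% of the truth in 100% of 419 unscaled and 385 scaled cases. All scaled cases were drawn with a whole-number background, so ethylene regions solved by the median of candidates were not covered. Simulated backgrounds also stayed below those of air regions at 10 or more times the floor. The same held for ethylene regions at 3 or more times the floor, so neither group was covered.

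The gene list test was tested on simulated data over the same 27444 genes, with summits placed at random along the chromosomes. It made 0 calls in 340 tests of lists without an effect. A planted list of 20 genes with summits added to 20% of its members was called in 2 of 20 draws, and with summits added to 40% in 20 of 20 draws. The real summits lay mostly near gene ends, so these rates need not hold for the real lists. The alternatives varied the overlap rule, the number of regions, the ranking, the flank, the window around gene ends and the background genes. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.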

Results

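The series measured where ENAP1, a nuclear protein that associates with EIN2 and with histones, sat on the genome of dark-grown Arabidopsis seedlings. The seedlings lacked EIN3 and EIL1, the transcription factors that act at the end of the ethylene pathway, so the binding recorded was that found without them. The study compared seedlings kept for 4 h in air with seedlings given 10 ppm ethylene. Each treatment had 2 ChIP and 2 input samples, and the authors' processing turned them into 1 list of bound regions per treatment. No value per replicate entered the comparison, so no region was tested between treatments, and a region absent from a list was not shown to be unbound.

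The air list held 4526 regions and the ethylene list 3293. In both, the highest fold enrichment lay at GATB (AT1G48520), which encodes a subunit of an organellar aminoacyl-tRNA amidotransferase. There the deposited enrichment over background was 22.4 in air (chromosome 1, 17939887 to 17940207, TAIR10) and 8.75 in ethylene (17939901 to 17940312), with the summit 21 bp inside a gene end. RALFL22 (AT3G05490), a gene of a RALF-like signalling peptide, and APD1 (AT2G38185) were also among the 10 highest of both lists, at ranks 9 and 5 in air and ranks 6 and 7 in ethylene. The other air regions of that group lay at AT3G06660, STL2P, SCI1, UBP6, AT2G26730, AT1G57600 and PHB2, with enrichments of 18.9 to 21.7. The other ethylene regions lay at AT1G48200, TOE2, AT1G19430, ETR2, AT1G76630, VEL1 and AT1G08910, with enrichments of 7.48 to 7.90. ETR2 encodes an ethylene receptor, TOE2 an AP2-type transcription factor and UBP6 a ubiquitin-specific protease.

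Regions were short in both lists, with a median width of 225 bp in air (interquartile range 183 to 285) and 237 bp in ethylene (195 to 297). They covered 1122 kb, or 0.942% of the 5 chromosomes, in air and 855 kb, or 0.718%, in ethylene. Median fold enrichment was 5.06 in air (interquartile range 4.18 to 6.45) and 2.84 in ethylene (2.42 to 3.45). The −log10 p values ran from 10.7 to 161 in air and from 8.43 to 92.2 in ethylene. The median pile-up at a summit was 48.0 in air and 89.7 in ethylene, over a median local background of 8.13 and 28.0. These quantities belong to each list's own scale and carry no replicate error.

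Both lists followed the gene-rich chromosome arms and thinned out around the centromeres. Per 100 protein-coding genes, the air list held 15.7 regions on chromosome 4 and 17.4 on chromosome 5, with the other chromosomes between them. The ethylene list ranged from 11.4 on chromosome 4 to 12.6 on chromosome 2. Over 240 bins of 500 kb, the number of regions followed the number of genes with Pearson r = 0.81 and Spearman rho = 0.74 in air, and r = 0.79 and rho = 0.68 in ethylene. The bins are stretches of 1 genome and not independent replicates. In the 24 bins with the fewest genes, density fell to 10.2 regions per 100 genes in air and 7.61 in ethylene, against 16.5 and 12.0 over all bins.

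**Figure D1:**
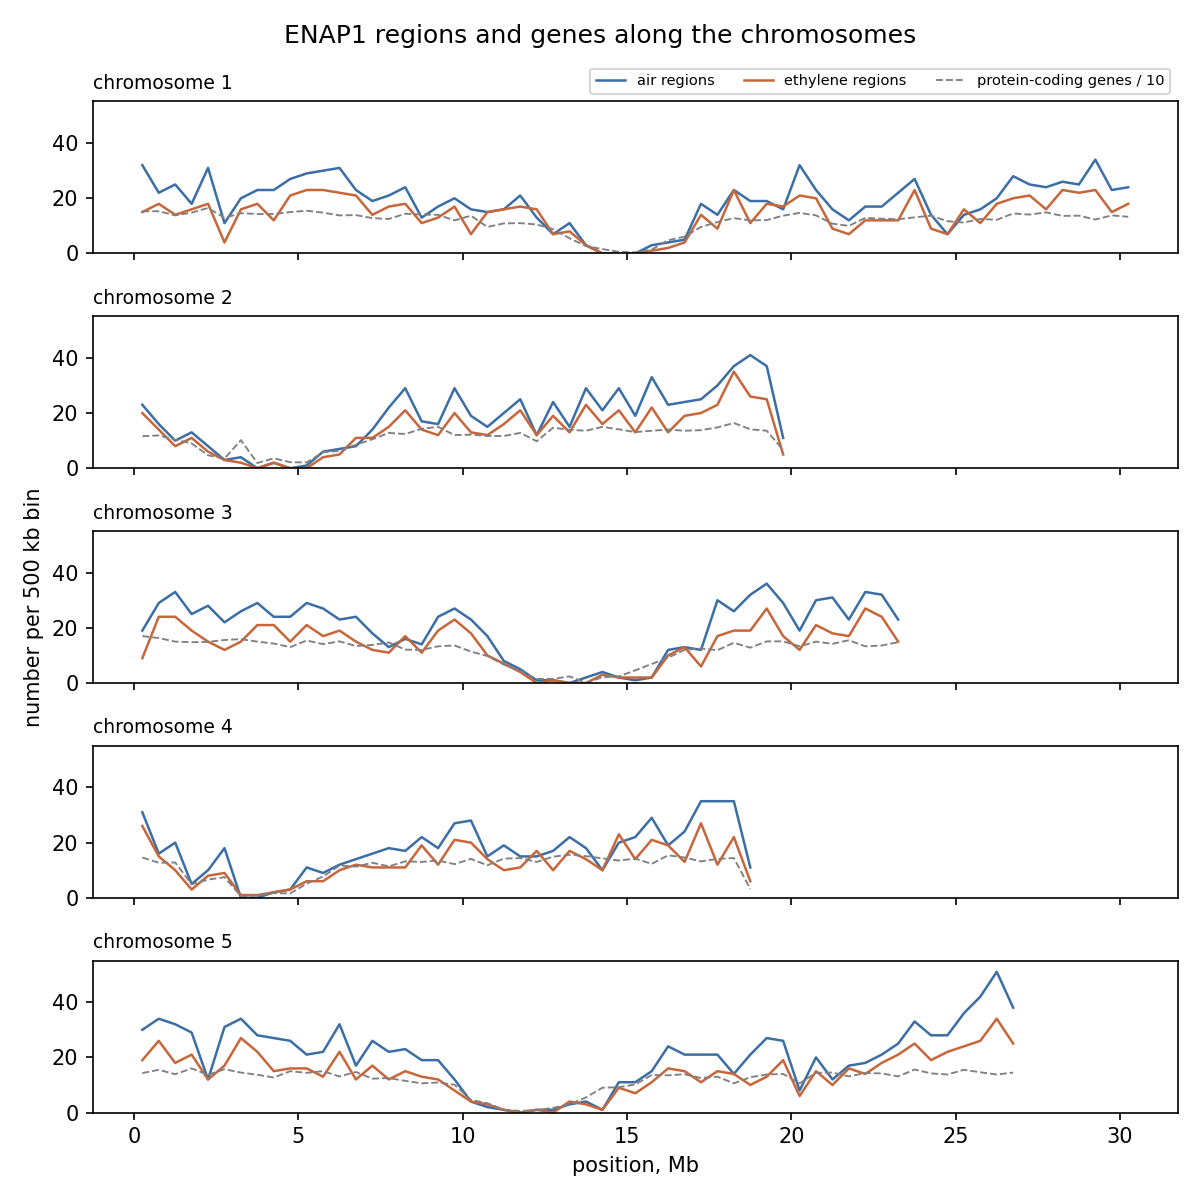
Number of ENAP1 regions in the air list (blue) and the ethylene list (orange) per 500 kb bin along chromosomes 1 to 5, with the number of protein-coding genes divided by 10 (dashed grey). The x axis is position in Mb; both lists follow gene number (Pearson r = 0.81 in air and 0.79 in ethylene) and drop to near 0 around the centromeres.

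The first comparison asked how far the regions bound in air were those bound after ethylene. Most of the ethylene list was present in the air list. Of the 3293 ethylene regions 2655, or 80.6% (95% interval 79.2 to 82.0), overlapped an air region, and of the 4526 air regions 2659, or 58.7% (57.3 to 60.2), overlapped an ethylene region. The shared regions included all 10 regions with the highest fold enrichment of each list, among them GATB, ETR2, UBP6, PHB2 and TOE2. Random placement along the chromosomes gave 1.40% for the air list and 1.92% for the ethylene list. Placement at the same distance from random gene ends gave 4.18% and 5.75%, with a highest value of 5.26% and 7.20% in 10000 placements. For both lists and both kinds of placement the one-sided permutation p was 0.0001, the smallest possible.

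The 1867 air-only and 638 ethylene-only regions were mostly in the lower part of their lists by −log10 p, and the ethylene-only regions less so by fold enrichment. The highest air-only regions by fold enrichment lay at AT4G08170 (enrichment 10.7), AT1G45015, OTLD1, AT5G51340, ISU1, AT3G62810, BGLU25 and ASPG1 (7.98). OTLD1 encodes an otubain-like deubiquitinase of histones and ISU1 a scaffold for iron-sulfur clusters. The first of them held rank 214 of 4526. The highest ethylene-only regions lay at AT1G23970 (enrichment 4.80), COB, AT3G09720, GPX7, AT5G49580, GLX2-5, AT4G16150 and HEC2 (4.05). COB encodes a cell surface protein needed for oriented cell expansion and GPX7 a glutathione peroxidase. The first of these held rank 203 of 3293. Of the air-only regions 76.6% (74.7 to 78.5) lay below the median −log10 p of the air list, and of the ethylene-only regions 85.4% (82.4 to 88.1) below that of the ethylene list. Below the median fold enrichment lay 77.6% of air-only and 57.8% of ethylene-only regions.

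Sharing rose with rank in the air list. From the lowest to the highest quartile of fold enrichment it was 26.1% (23.6 to 28.8), 44.7%, 69.7% and 94.5% (93.0 to 95.8). In the ethylene list it was 87.5% (85.0 to 89.7), 67.6%, 73.9% and 93.6% (91.7 to 95.1), so the lowest quartile was shared more often than those above it except the highest. That lowest ethylene quartile had a median local background of 50.7, against 28.0, 22.6 and 21 in the others. Ranked by −log10 p, sharing rose through all quartiles of the ethylene list, from 60.7% to 99.0%. The highest and lowest quartiles by fold enrichment differed by 68.4 percentage points in air (Fisher exact test, two-sided, p = 5.29e-275) and by 6.06 in ethylene (p = 3.28e-05). Both p-values treat the regions of a list as independent and carry no variation between replicates.

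**Figure D2:**
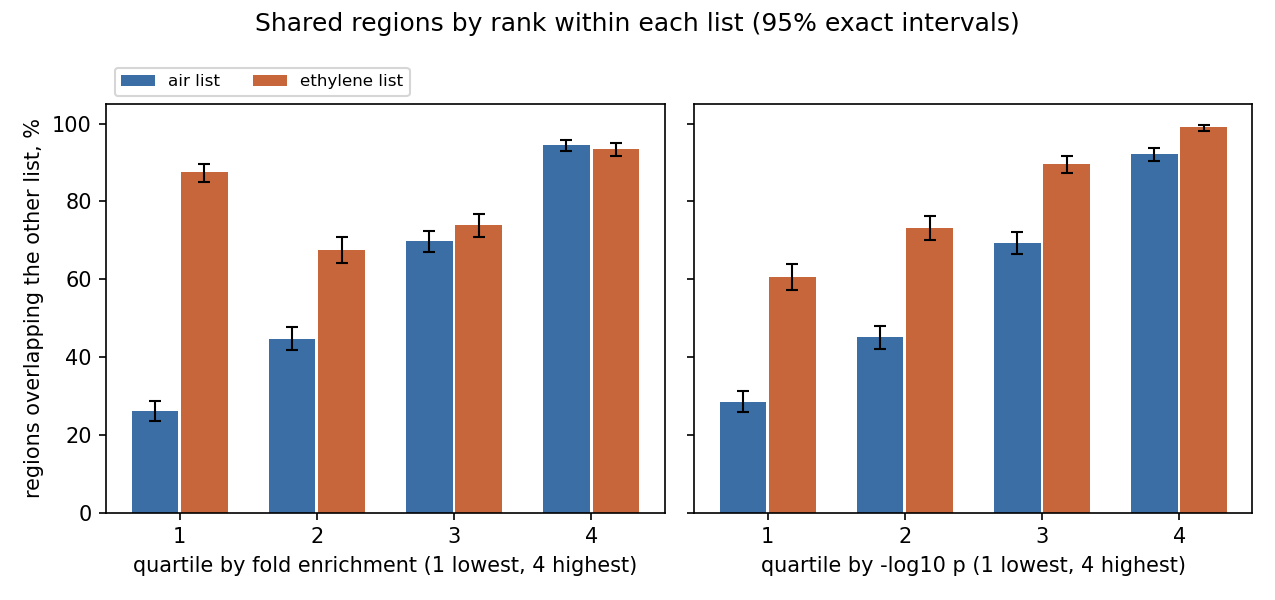
Share of regions that overlap a region of the other list, in % (y axis), by quartile within the air list (blue) and the ethylene list (orange), ranked by fold enrichment (left) or by −log10 p (right). Error bars are exact 95% binomial intervals; the highest quartile by fold enrichment was shared at 94.5% in air and 93.6% in ethylene.

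The second comparison asked where in relation to genes ENAP1 was found. Summits in both lists were concentrated just inside the ends of protein-coding genes. At GATB the summit was 21 bp inside, at AT1G76630 13 bp inside and at AT1G19430 12 bp inside an end, while at AT3G06660 it was 28 bp outside. In air 75.8% of summits (74.5 to 77.0) and in ethylene 77.5% (76.1 to 78.9) were inside a protein-coding gene, against 54.2% and 54.1% of randomly placed summits. Those within 500 bp of the end made up 68.3% in air and 71.4% in ethylene, where 21.3% was the random share for both. Deeper inside a gene lay 7.47% and 6.16%, against a random share of 32.8%. Inside other annotated genes, such as those of noncoding RNAs, lay 3.60% and 3.74%, against 9.97%. More than 1000 bp away from any protein-coding gene and outside other annotated genes lay 3.09% and 3.37%, against 16.8%. All these differences had a two-sided permutation p of 0.0002, the smallest possible.

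The band up to 1000 bp outside genes held 17.5% of air summits (16.4 to 18.7) and 15.4% of ethylene summits (14.2 to 16.6), against 19.04% placed at random (two-sided permutation p = 0.0102 in air and 0.0002 in ethylene). The air difference over 1000 bp did not pass the threshold once regions at 5 or more times the background floor were removed. Counted over 500 bp, the band held more air summits than random placement, 15.1% against 12.6% (permutation p = 0.002), and 12.8% of ethylene summits against 12.6% (permutation p = 0.8). Which end of a gene was the transcription start was not determined. No class separated air-only from ethylene-only regions. More than 500 bp inside a gene lay 10.0% (8.69 to 11.5) of air-only and 7.21% (5.33 to 9.50) of ethylene-only summits (Fisher exact test, two-sided, p = 0.0398, adjusted p = 0.109 over 5 classes). Of the other 4 classes, the lowest adjusted p was also 0.109, so none passed the threshold.

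**Figure D3:**
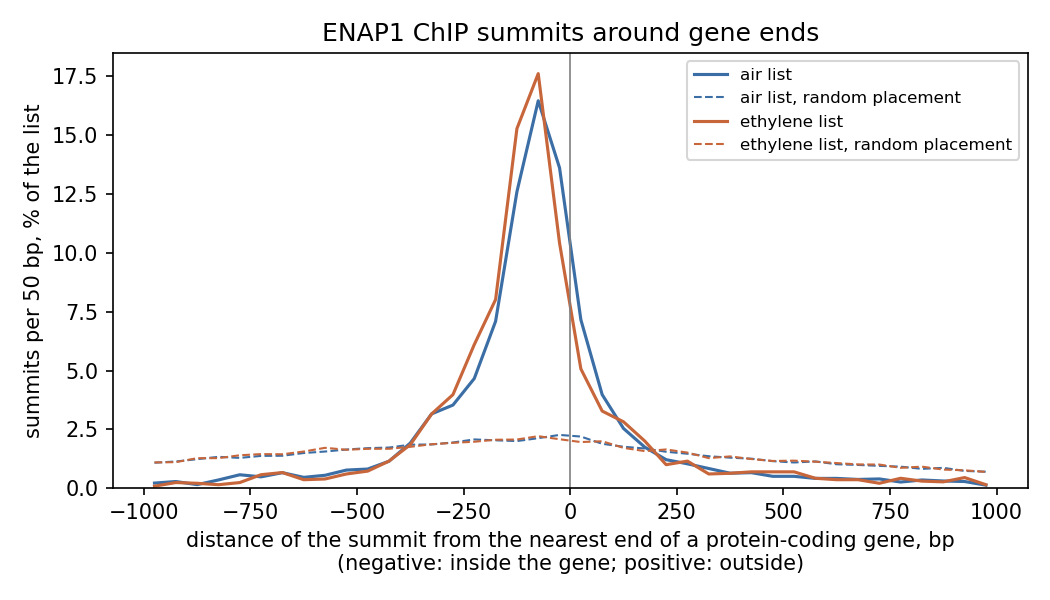
Share of summits per 50 bp, in % of the list (y axis), by distance in bp from the nearest end of a protein-coding gene (x axis; negative inside, positive outside), for the air list (blue) and the ethylene list (orange), with random placements dashed. The peak lies just inside the gene end, where the first 200 bp held 50.0% of air summits and 51.4% of ethylene summits.

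The third comparison asked which genes carried ENAP1, first among those of the ethylene pathway. Of 19 ethylene signalling genes, 6 were bound in both lists, namely the receptor genes ETR1, ETR2 and EIN4, the central regulator EIN2, the exoribonuclease gene XRN4 and ENAP1 itself. ERS2, another receptor gene, and EIL1 were bound in the ethylene list only, and EIN3 in neither. At ETR2 (AT3G23150) the ethylene region had rank 5 with an enrichment of 7.66 (chromosome 3, 8254526 to 8254878) and the air region rank 322 with 9.79 (8254503 to 8254837), with summits 137 and 111 bp inside a gene end. At EIN2 (AT5G03280) the air region had rank 107 with an enrichment of 12.6 (chromosome 5, 793280 to 794006) and the ethylene region rank 1372 with 3.01 (793377 to 793820), with summits 250 and 254 bp outside. ETR1 had enrichments of 8.64 in air and 4.23 in ethylene, XRN4 8.82 and 4.84, and EIN4 5.19 and 2.63. The regions at ERS2 and EIL1 were low in the ethylene list, at ranks 2508 and 2033. At ENAP1 (AT3G11100) the enrichment was 5.76 in air (chromosome 3, 3477231 to 3477593) and 2.08 in ethylene. The local background there was among the highest of both lists, at 6.31 times the floor in air and 5.38 times in ethylene. Any added copy of the gene that encodes the tagged protein would also give reads at this locus, which was not tested.

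In the ethylene list the 8 bound members made up 42.1% (20.3 to 66.5) of ethylene signalling genes, against 15.9% of other genes (odds ratio 3.92, Fisher exact test, two-sided, p = 0.00581, adjusted p = 0.0494 over 17 lists). ENAP1 itself, at a locus of high local background, is among these 8. The call was lost under 6 of 8 alternatives, among them random gene sets of the same gene length. These had a mean of 3.66 bound genes, against the 8 observed (permutation p = 0.0364, adjusted p = 0.309). In the air list the 6 bound members made up 31.6% against 20.9% (Fisher exact test, adjusted p = 0.633). The difference between lists, 0 air-only and 2 ethylene-only members, gave a Fisher exact p of 0.0637 and an adjusted p of 1. Among 25 targets of EIN3, EDF3 and ETR2 were bound in both lists, ARGOS and ARL in air only and ERS2 in ethylene only. That is 4 in air and 3 in ethylene, or 16.0% and 12.0%, against 20.96% and 15.9% of other genes (Fisher exact test, adjusted p = 1 and 0.956). Of 19 ethylene biosynthesis genes, MAT3 was bound in both lists, EOL2 in air only and ACS6 in ethylene only (Fisher exact test, adjusted p = 0.753 in air and 0.956 in ethylene).

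Over the genome, 5751 genes (20.96%) were bound in the air list and 4356 (15.9%) in the ethylene list. Both lists shared 3644 genes, where independent lists of these sizes would share 913. Bound in air only were 2107 genes and in ethylene only 712.

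Of the remaining lists, housekeeping genes had the highest bound share in both peak lists. The housekeeping genes ACT2, UBQ10, GAPC1 and PP2AA3 were bound in both lists, 4 of 5 members. That passed the threshold of Fisher's exact test in ethylene (odds ratio 15.9, adjusted p = 0.0470) and not in air (odds ratio 11.3, adjusted p = 0.0615), and the ethylene call was lost under 5 of 8 alternatives, with exact or permutation adjusted p from 0.00475 to 0.197 over all 8. The highest was against random sets of the same gene length, which had a mean of 0.977 bound genes against the 4 observed (permutation p = 0.0116). In air the list passed with the 500 bp window (Fisher exact test, adjusted p = 0.0230) and with each summit counted for the nearest gene end only (adjusted p = 0.0146). At GAPC1 the highest region differed between lists, as the air one (chromosome 3, 1083800 to 1084046) was air-only and the ethylene one (1080830 to 1081091) shared. The summit of that air region lay 221 bp outside GAPC1 and 139 bp inside the neighbouring gene AT3G04130. None of 10 flower identity genes and none of 11 genes of shoot epidermis, guard cells and shoot meristem was bound in either list. With 0 members bound, the exact intervals reached 30.8% and 28.5%, so these lists were not told apart from other genes (adjusted p = 0.384 for both in air and 0.647 for both in ethylene).

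Among 17 clock genes 8 were bound in air (47.1%, Fisher exact test, adjusted p = 0.0615) and 6 in ethylene (35.3%, adjusted p = 0.231). TOC1 (AT5G61380), a core repressor of the clock, had rank 31 in air with an enrichment of 15.9 (chromosome 5, 24675019 to 24675275) and rank 49 in ethylene with 6.12. ZTL, GI, PRR7 and LNK1 were also bound in both lists. Of 26 ERF transcription factor genes 11 were bound in air (42.3%, Fisher exact test, adjusted p = 0.0615) and 6 in ethylene (23.1%, adjusted p = 0.647), with ERF4, ERF9, ERF12 and ERF104 in both, ERF6 and ERF7 in air only and ERF8 in ethylene only. Against random sets of the same gene length the ERF list passed in air (adjusted permutation p = 0.0408). Of 19 jasmonate genes 9 were bound in air (47.4%, Fisher exact test, adjusted p = 0.0615) and 5 in ethylene (26.3%, adjusted p = 0.647). JAZ2 and JAZ6, which encode repressors of the pathway, and the transcription factor genes MYC3 and MYC4 were in both, while JAZ1 and AOS were in air only. The clock, ERF and jasmonate lists, like the housekeeping list, each passed the threshold in air under at least 1 other window, assignment or background, so their calls depend on that choice. Other choices can lower a share. The highest air regions at ERF7 (502 bp outside), ERF9 (201 bp inside), ERF12 (823 bp outside) and ERF104 (375 bp inside) fell beyond the short window. That window runs from 500 bp outside to 200 bp inside a gene end.

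The other lists did not pass in either peak list. In air and ethylene, bound members numbered 6 and 5 of 31 auxin genes (ARF6 and ARF8 highest in both), 5 and 2 of 20 gibberellin and brassinosteroid genes (GID1B and BIN2 in both), 4 and 1 of 21 light signalling genes (PIF5 in both, HY5 in air only) and 5 and 3 of 23 rapid stress genes (ERF104, ERF5 and MPK3 in both, ZAT10 in air only). Cytokinin response had 2 and 2 of 13 (ARR6 in both), photosynthesis and chlorophyll 2 and 2 of 19 (LHCA3 in both), and root identity 2 and 2 of 8, where the root regulators SCR and WOX5 were bound in both. Histone acetylation had 1 and 0 of 9, with HAG1 in air. The adjusted p of these lists lay between 0.647 and 1.

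No gene list differed between genes bound only in air and genes bound only in ethylene. By Fisher's exact test, 0 of 17 lists had an adjusted p under the threshold and 0 had an unadjusted p under it. The largest group of 1 kind was the 6 air-only ERF genes, beside 1 ethylene-only (Fisher exact test, adjusted p = 1). Few members per list were bound in 1 list only, which limits this test.

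**Figure D4:**
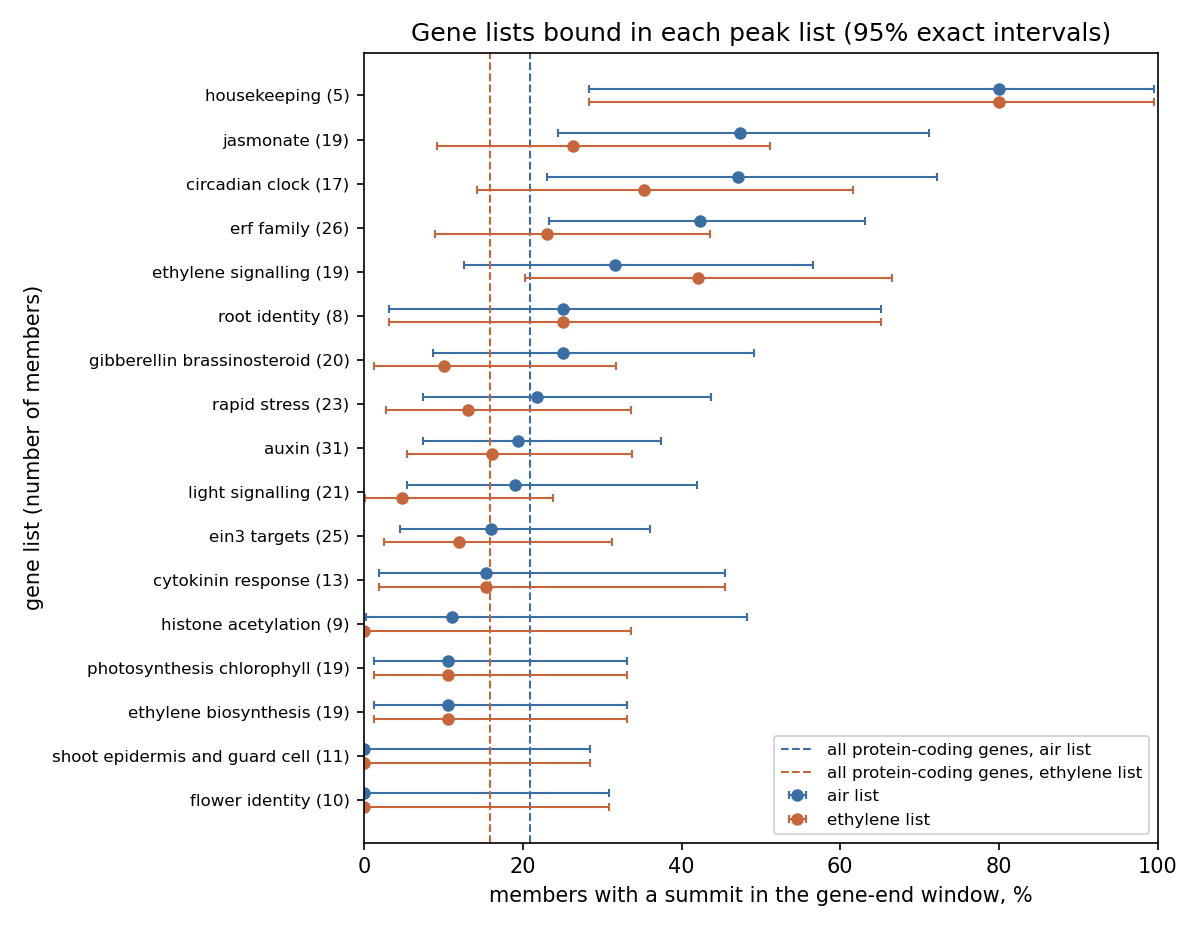
Share of members with a summit in the gene-end window, in % (x axis), for each of 17 gene lists with its number of members (y axis), in the air list (blue) and the ethylene list (orange), with exact 95% intervals. Dashed lines mark all protein-coding genes, 20.96% in air and 15.9% in ethylene; housekeeping genes reached 80.0% in both lists, and flower identity genes 0%.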

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

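No paired analysis was possible because each treatment has 1 joint list with no value per replicate, and leaving out a replicate was not possible for the same reason. The alternatives that remove regions at 5 or more times the background floor, assign a summit to the nearest gene end only, or match gene length were chosen after seeing the data. Motif and 6-mer alternatives were not run. Sharing stayed above gene-end placement under all 6 alternatives, at 55.6% to 70.5% in air and 70.5% to 80.0% in ethylene, and summits inside genes above random placement under 3, at 75.1% to 80.5% and 76.9% to 78.7%. The upper 50% by −log10 p held 2263 and 1646 regions by construction.

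The band outside genes turned above random with a 500 bp flank, at 15.1% in air and 12.8% in ethylene (the latter not past the threshold). It was 18.2% in air without high-background regions (permutation p = 0.182). The cause was not tested.

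In air, lists past the threshold rose from 0 to 2 with the 500 bp or 2000 bp window or the nearest end, and to 1 over whole genes or with matched length. In ethylene they fell from 2 to 1 with the 500 bp window, and to 0 with the 2000 bp window, region overlap, the upper 50%, genes with a symbol or matched length. Ethylene signalling in ethylene then had 31.6% of members bound (500 bp window), 26.3% (upper 50%) or 42.1% (the other 4), with adjusted p from 0.00475 to 0.309 over all 8 alternatives. The cause was not tested. No list differed between air-only and ethylene-only genes in any of 6 alternatives (Fisher's exact test, with 1 list at an unadjusted p under 0.05 over whole genes and 0 in the others). Of 264 values for other lists, 251 kept their side of the threshold, 5 lost and 8 gained the call. Direction was compared only where a call was made, with 0 reversals, so values without a call may have changed direction. List sizes of 5 to 31 genes limit these tests.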

Other observations

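All tests in this part were chosen after the data were seen. Among 172 gene families grouped by symbol, with at least 10 members each, cytochrome P450 genes (the group named CYP, which also takes in the cyclophilins CYP5 and CYP59) were bound less often than other genes. In air 26 of 229 were bound (11.4% against 21.04%, Fisher exact test, two-sided, adjusted p = 0.0141), and in ethylene 17 (7.42% against 15.9%, adjusted p = 0.0308). Random genes of the same length gave means of 53.3 and 39.8, with a permutation p of 0.0002 in both, the smallest possible (adjusted p = 0.0344 over the families). Bound members included CYP707A1 and CYP707A3, which break down abscisic acid, and CYP98A3 of phenylpropanoid synthesis in air only. Peroxin genes, needed to build peroxisomes, were bound more often in air, 11 of 19 (57.9% against 20.9%, Fisher exact test, adjusted p = 0.0271), among them PEX5, PEX7, PEX10, PEX13 and PEX14. Random genes of the same length gave a mean of 4.44 (permutation p = 0.0038, adjusted p = 0.151), so this call was lost when gene length was matched. In ethylene 6 of 19 were bound (Fisher exact test, adjusted p = 0.663), and the difference was not tested. Members of a family can be neighbours that share a summit, so these p-values are approximate. Genes named LCR, which encode small cysteine-rich proteins, were bound at 4 of 80 in air (adjusted p = 0.0141), where random genes of the same length gave a mean of 8.62 (permutation p = 0.114, adjusted p = 0.736).

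Transfer RNA and long noncoding RNA genes had a summit within 500 bp more often than placement at the same distance from random gene ends gave. For transfer RNA genes this was 68 of 625 in air, against a mean of 42.8, and 51 in ethylene, against 31.5. For long noncoding RNA genes it was 305 of 3480 against 228 and 234 against 169. Each of the 4 had an adjusted permutation p of 0.006. A summit within 500 bp can also lie in or beside a protein-coding gene, and such summits were not separated. Inside other annotated genes and outside protein-coding ones, summits were fewer than random placement along the chromosomes gave. They made up 3.60% in air and 3.74% in ethylene, against 9.97%. MicroRNA, small nuclear RNA and pseudogene classes did not pass, with an adjusted permutation p of 0.0920 or more, nor did small nucleolar RNA genes, at 0.0720 in air and 0.584 in ethylene.

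The local background, solved from the deposited fold and p and divided by the floor of the list, ranked shared regions in a similar order in both lists. Across 2659 air regions and the ethylene regions they overlapped, Spearman's rho was 0.848 for that background and 0.540 for fold enrichment. Regions are not independent replicates. By background, the ENAP1 locus was among the highest in both lists, at 6.31 times the floor in air (rank 76 of 4526) and 5.38 times in ethylene (rank 42 of 3293). No test here bears on why.

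Sharing moved in opposite directions with that background. In air it fell from 63.7% (61.6 to 65.7) of regions under 2 times the floor to 62.5% at 2 to 3 times, 50.6% at 3 to 5 times and 19.9% (14.7 to 26.0) of the 206 regions at 5 or more times. In ethylene it rose from 70.1% (68.0 to 72.2) to 90.3%, 97.0% and 97.6% (91.7 to 99.7), the last over 84 regions. The air list had 17 regions at 10 or more times the floor, of which 0 were shared, and the ethylene list had 0. The fold enrichments of these 17 regions were 1.67 to 3.84, all below the air median of 5.06. Whether repeated sequence adds reads at them was not tested. The highest reached 29.6 times the floor in air and 6.74 times in ethylene.

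The ethylene list held fewer regions at lower fold enrichment than the air list. Shallower ethylene libraries would give a lower floor, but the floor was higher in ethylene, by 3.17 times after division by the ratio of the smallest region widths (148 and 122 bp), which argues against a lack of depth. A stricter p threshold would give a higher lowest −log10 p in ethylene, but the lowest was 8.43, below the 10.7 of air. Both are end points after the authors' selection of regions, by a rule not given here. They cannot decide whether the caller's threshold or that rule was stricter for ethylene. A lower yield of the ethylene immunoprecipitation and a change in binding after ethylene would both lower fold enrichment (median 2.84 against 5.06). The ethylene list also had a higher local background (median 28.0 against 8.13) and a lower end point of −log10 p. Both let regions of lower fold enrichment enter that list. With 1 list per treatment these cannot be told apart.

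Of the regions found in 1 list only, 76.6% in air and 85.4% in ethylene lay below the list's median −log10 p, but signal just short of the other list's end point cannot be told apart from lost binding, since signal outside the lists was not used here. In the top quartile by −log10 p, 89 of 1132 air regions were air-only and 8 of 824 ethylene regions ethylene-only. For the air-only ones the median background was 4.13 times the floor, against 2.19 for shared regions of that quartile (two-sided permutation p = 1e-05, the smallest possible), but the 8 ethylene-only regions went the other way, at 1.19 against 1.85 (permutation p = 0.0393). Because background was solved from fold and p, a high value at high −log10 p restates a low fold, so a role of local background stays open, as does binding that depends on treatment. The 5 highest air-only regions by −log10 p lay near MYB102 (5.49 fold, chromosome 4, 11416614 to 11417087), AT5G41860, AT5G11550, AT1G75960 and PUB19, named after their values were seen.

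Regions lay mostly at gene ends. Of air regions 52.7% and of ethylene regions 45.2% had a local background of 2 or more times the floor. That floor is the lowest background the caller uses, and the background at positions outside the regions was not measured. Whether input chromatin is itself richer at the regions was therefore not decided. The fold enrichment is measured over the local background, and no immunoprecipitation from seedlings without the tagged protein was used here. Enrichment of open chromatin in any immunoprecipitate and binding by ENAP1 therefore cannot be told apart.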
